A study of Mus musculus with 2 samples.

How the data were processed

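Total RNA-seq of the adrenal gland of female B6CASTF1/J mice at day 14 was analysed, 1 group of 2 libraries. Per the labels, each library was made from 300 ng of RNA with a directional kit after ribosomal RNA reduction, with ERCC spike-ins. Each library's replicate number was taken from its label. The text deposited with each sample gives the assembly mm10 and the GENCODE annotation M21, and says that the gene table and the first transcript table derive from a transcriptome alignment and the second transcript table from read files and an index. The tools and versions that made them are not given in the sources used here, and neither is whether counting used strand. Per the file headers, the gene table and the first transcript table hold the authors' expected counts and TPM, with the percent of a gene's TPM given to each transcript in a column of the deposited transcript table. The second transcript table holds estimated counts and TPM per the file headers. TPM in each deposited table is relative to all its entries. In the first transcript table the effective length was 99 bases under the length for all transcripts of at least 1000 bases in both libraries, so no fragment length of the library entered it. In the second table the median difference was 300.0 and 321 bases for transcripts of at least 5000 bases. Expected counts were whole for 94.7% and 94.96% of genes, to 2 decimals.

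All 55536 GENCODE genes of the gene table were found in the reference annotation of the same release, which gave symbols, classes and mm10 coordinates counted from 1. Genes that share a symbol were summed. The gene table also has 96 ERCC entries and 26248 tRNA entries. Of its GENCODE genes, 86 have no transcript in the second table. Expected counts were rounded to whole numbers. Library totals were 37586172 and 33844950 expected counts, and 38435728 and 32908120 estimated counts in the second table. At these depths a count of 0 allows up to 3 counts, or 7.98e-06% and 8.86e-06% of the counts. A fold against 0 counts was computed against that floor per library and is given as a lower bound.

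Before the data were examined, the tests, 35 gene lists (467 genes, of which 466 matched), 15 gene pairs and 36 processing alternatives were fixed. The rule for named genes was fixed too: list members, the 20 genes of highest mean TPM, the 10 genes per direction with the largest replicate difference among those with a mean count of at least 100 that differed beyond counting noise, the 10 per direction with the largest difference between the transcript tables among those of at least 10 TPM, and spike-ins. Counts were scaled with edgeR's TMM, and dispersion came from an intercept-only edgeR fit after its expression filter. The interval of the dispersion came from 50 resamplings of genes with edgeR's direct common estimate, not the one reported. Differences are log2 of replicate 2 over replicate 1 with a prior count of 0.5. Genes with a mean count of at least 20, mitochondrial genes left out, entered the fold counts and the exact conditional binomial test (two-sided, doubled smaller tail, Benjamini-Hochberg under 0.05). For each list, the median difference of genes with a mean count of at least 10 was ranked among 10000 random lists of the same size matched on mean count in 20 bins, and its median TPM among random lists of protein-coding genes. Intervals of a fold are Clopper-Pearson intervals at 95%, and those of a median come from order statistics. For each spike-in the 10 genes nearest in mean count were taken as its match. Transcript tables were compared as log2(TPM + 1) summed to genes. No test between groups was possible with 1 group.

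Alternatives covered DESeq2 size factors, spike-in and total-count scaling, count and TPM minimums, pseudocounts, the second table, rescaled TPM and leaving out each replicate. The comparison of tables relative to the median gene was added after the values were seen. Also chosen after the values were seen were the lists of other liver cells (Kupffer, sinusoidal, stellate and bile duct), thymocytes, thymus epithelium, B lymphocytes, fat not shared with liver or muscle, and muscle genes near absent from replicate 1 for a carry-over check, the blocks of genes over 16-fold apart, and a second test of blood on T cell genes, added when the first was undecided. A test of carry-over over all genes with a mean count of at least 20 (Poisson, Bonferroni under 0.05) was added too. In the thymus epithelium list, and in the muscle genes of the carry-over check where stated, a count of 0 was set to the floor. Scripts were tested on simulated counts. For the calls, counts were drawn with Poisson noise alone, scaled by library totals, and only a small set of genes was changed. Of 16178 genes, those changed 1.5-fold were called the right way in 79.0% and those changed 3-fold in 98.0%, and 4.32% of calls were false. These shares hold for counting noise only and give no error rate for the calls between the real libraries. In a separate simulation, biological coefficients of variation (square roots of the dispersion) of 0.1 and 0.3 came back as 0.0988 and 0.294. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used. Alignments and signal tracks were not used here. Values of some single list members, and of 1 pair, are not reported here.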

Results

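Total RNA, with ribosomal RNA reduced and ERCC spike-ins added (a set of synthetic RNAs at known amounts), was sequenced from the adrenal gland of female mice 14 days old. The mice were of the F1 hybrid strain B6CASTF1/J, and 300 ng of RNA went into each library. The labels name 1 group with 2 biological replicates, so the only comparison the design holds is between these libraries. The expected counts summed to 37586172 in replicate 1 and 33844950 in replicate 2. ERCC spike-ins took 0.337% (95% Wilson interval 0.335 to 0.339) and 0.322% (0.320 to 0.324) of the counts. Both libraries carry the same donor identifier and the same pooled-female library description, while the tissue label of replicate 2 names a single numbered female. Whether the replicates are separate animals was therefore not settled, and the spread between them may be partly technical. Floors and the intervals of a fold or of a share of counts cover counting error only. Intervals of a list median, or of a difference of medians, reflect the spread across the genes and treat these as independent. The interval of the spike-in spread, and of the ratio of gene to spike-in spread, comes from resampling spike-ins only. None covers variation between animals.

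Transcripts of adrenal steroid synthesis were among the high protein-coding signals of the tissue. Star, whose protein brings cholesterol into mitochondria, stood at 1443 ± 857 TPM (SD, n = 2). Cyp11a1, which makes pregnenolone from cholesterol, stood at 860 ± 484 TPM (SD, n = 2). Cyp11b1, the last enzyme of corticosterone synthesis, reached 618 ± 374 TPM (SD, n = 2), and Cyp11b2, the aldosterone synthase, 29.8 ± 15.1 TPM (SD, n = 2). Hsd3b1 stood at 2072 ± 1128 TPM and Cyp21a1 at 993 ± 501 TPM (SD, n = 2), both sharing sequence with near copies, so that the authors' counting could split their reads. The large SDs come from lower values in replicate 2 for each of these 6 genes. In mm10, Star lies on chromosome 8 from 25806555 to 25815982 and Cyp11a1 on chromosome 9 from 58006411 to 58027023. Cyp11b1 (74834125 to 74841643) and Cyp11b2 (74851010 to 74856318) are neighbours on chromosome 15, both on the minus strand.

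The median member of the steroid synthesis list had 53.6 TPM in replicate 1 and 68.7 TPM in replicate 2 (percentile 100 among random lists of protein-coding genes). Cortical identity genes had median levels of 30.3 and 16.7 TPM, zona fasciculata genes 184 and 94.2 TPM, zona glomerulosa genes 14.8 and 9.79 TPM, and genes of the X-zone, the transient inner cortex of the mouse, 21.8 and 11.7 TPM. Chromaffin cell genes, which mark the catecholamine-making medulla, had medians of 10.6 and 5.93 TPM. Th, the first enzyme of catecholamine synthesis, was at 120 ± 76.8 TPM (SD, n = 2), and Chga, a secretory granule protein, at 372 ± 192 TPM (SD, n = 2). The X-zone and chromaffin lists, at percentiles 97.3 and 94.2, did not stand apart from random lists for level. X-zone genes did so in the second transcript table (percentile 99.2, mean level 34.6 against 16.7 TPM) and without replicate 2 (98.55). The glomerulosa list, at 98.3, lay inside the random range in the second table (97.2), without replicate 1 (96.7) and over members of at least 1 TPM (89.2). Of 35 lists, 20 lay above percentile 97.5, among them endothelial genes at 24.7 and 17.4 TPM, capsule and stroma genes at 27.1 and 23.2 TPM, and cholesterol synthesis genes at 17.4 and 10.98 TPM (percentile 97.1 over members of at least 1 TPM). Liver (percentile 100) and skeletal muscle genes (99.5) were among the 20 too, but lay at 89.6 and 19.2 without replicate 2.

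Markers of fat were present too. Ucp1, the uncoupling protein of brown fat, was at 716 ± 81.4 TPM (SD, n = 2), Cidea, a lipid droplet protein, at 304 ± 38.7 TPM and Adipoq, the fat hormone adiponectin, at 69.7 ± 9.24 TPM (SD, n = 2). The white adipocyte list had median levels of 92.8 and 94.97 TPM (percentile 100) and the brown adipocyte list 10.8 and 11.6 TPM (percentile 94.5, not apart from random lists). No member of the kidney list reached 1 TPM in either library. The median member was at 0.0350 and 0 TPM for exocrine pancreas, and at 0.0800 TPM in both libraries for gonad. Of the exocrine pancreas list, 2 members reached 1 TPM in replicate 1 and 1 in replicate 2. Of the gonad list, 1 member did so in each library. The 8 Y-linked genes together had 2 counts in each library, under the floor of 3 counts, while Xist, the RNA that coats the inactive X chromosome, was at 53.4 ± 0.940 TPM (SD, n = 2).

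Several ratios within a library differed little between the replicates. Cyp11b1 exceeded Cyp11b2 21.8-fold in replicate 1 and 18.5-fold in replicate 2 (log2 4.33 ± 0.17, SD, n = 2), with log2 3.63 in the second transcript table and 5.33 as a ratio of counts. Cyp17a1, which directs steroids to cortisol and androgens, was 516-fold and 479-fold below Cyp11a1 (log2 -8.96 ± 0.08, -8.23 at a pseudocount of 1). Th stood below Cyp11a1 by 6.91-fold and 7.90-fold (log2 -2.89 ± 0.14), Pnmt, which makes adrenaline, exceeded Dbh 1.62-fold and 1.72-fold (but log2 -0.47 as a ratio of counts), and Ucp1 exceeded Adipoq 10.4-fold and 10.1-fold. The angiotensin receptor gene Agtr1a exceeded Agtr1b 16.1-fold and 17.2-fold (in the second table log2 -4.68 for Agtr1b to Agtr1a). Chgb exceeded Chga 1.10-fold and 1.14-fold (log2 0.75 as a ratio of counts). The ratios that differed most were Adipoq to Star (log2 -4.24 ± 1.10) and Star to Stard3 (log2 7.74 ± 0.82). The ratio of Akr1c18, a progesterone-degrading X-zone marker, to Cyp11b1 was 1.86 and 1.13 (log2 0.54 ± 0.51), about the size of its SD, and turned to -0.955 as a ratio of counts. Further log2 ratios (SD, n = 2) were 7.20 ± 0.24 for Hsd3b1 to Hsd3b6, 0.51 ± 0.32 for the vesicular monoamine transporters Slc18a1 to Slc18a2, -1.83 ± 0.46 for Igf2 to H19 and 0.35 ± 0.11 for Xist to Eif2s3x, which turned to -0.19 in the second transcript table and was 2.26 as a ratio of counts. With 2 libraries no exact test can reach a p of 0.05, so these ratios carry no test.

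Transcripts of liver and skeletal muscle were many times higher in replicate 2, and transcripts of T cells many times lower. Alb, the serum albumin of liver (chromosome 5, 90460897 to 90476602), was at 189 TPM in replicate 1 and 10582 TPM in replicate 2, 80.2-fold higher (95% interval 78.8 to 81.7). Myh1, a fast muscle myosin, was 326-fold higher (242 to 450). Rag1, the recombinase that assembles T and B cell receptors (chromosome 2, 101638282 to 101649501), had 1945 counts in replicate 1 and 7 in replicate 2, 198-fold higher in replicate 1 (95.8 to 493). Each value rests on 1 library, so no difference has a replicate check.

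All 12 liver genes were higher in replicate 2 (12 adjusted over the list alone), with a median log2 difference of 6.31 (95% interval 6.15 to 6.42, percentile 100). The lipid carrier Apoa1 was 79.1-fold higher, Ahsg 79.9-fold and the thyroxine carrier Ttr 99.4-fold, whereas Hp, haptoglobin, was 30.1-fold higher. Serpina1a and Serpina1b in this list share reads with near copies. The 9 measured skeletal muscle genes were higher too (9 adjusted over the list alone, median log2 4.75, 2.61 to 8.33), with the muscle actin Acta1 34.2-fold and the creatine kinase Ckm 23.0-fold higher. The muscle creatine kinase Ckmt2 had 0 counts in replicate 1 and 352 in replicate 2, at least 165-fold higher against a floor of 3 counts per library. The liver glucuronosyltransferase Ugt2a3 had 0 and 245 counts, at least 115-fold higher. Other genes with the largest differences upward were Myh2 (360-fold, 201 to 721), Afp, the fetal serum protein of liver (208-fold, 101 to 520), Sult2a5 (316-fold, 123 to 1163), Ces2a (227-fold, 110 to 565), Cyp2c69 (223-fold, 102 to 610), Iyd with 3 counts in replicate 1 (271-fold, 92.3 to 1319) and Smlr1 with 1 count in replicate 1 (308-fold, 54.6 to 12207).

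Lymphocyte genes had a median log2 difference of -3.72 over 11 measured members (95% interval -4.35 to 0.03, which reaches 0), of which 0 were higher, 7 lower and 4 not called (7 lower adjusted over the list alone). That median was -1.84 on the log2(TPM + 1) scale, -2.27 at a mean count of at least 1 and -2.83 in the second transcript table. Over 2-fold lower were 6 T cell genes, such as Cd8a (55.5-fold higher in replicate 1, 29.1 to 122), Cd3e (21.1-fold, 11.3 to 44.5) and Cd4 (17.6-fold, 10.5 to 31.8). The other called member was Ighm, an antibody heavy chain gene of B cells, at log2 -0.37, while the B cell gene Cd79a had 55 and 40 counts and was not called. Dntt, the polymerase that adds bases at receptor joints, had 288 counts in replicate 1 and 1 in replicate 2 (205-fold, 36.5 to 8125), Themis 320 and 2 (114-fold, 31.3 to 944), Ccr9 323 and 5 (46.0-fold, 19.5 to 143), and the receptor gene Trbc2 was 41.8-fold higher in replicate 1 (21.8 to 91.8). The processed pseudogenes Gm10163 (938 and 0 counts, at least 223-fold) and Gm10095 (87.6-fold, 29.7 to 427) and the gene Gm45062 (at least 50.7-fold) also led this direction, and their reads may belong to near-identical copies. Erythroid genes were lower in 9 of 9 (9 adjusted over the list alone, median log2 -1.34), with the beta-globin gene Hbb-bs and the heme synthesis gene Alas2 at log2 -1.34 and -1.29. The globin genes are near-identical copies.

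Adrenal genes were lower in replicate 2 and markers of fat and stroma higher, by amounts far below those of the liver genes. Of 16 tested steroid synthesis genes, 5 were higher, 10 lower and 1 not called (5 higher and 11 lower adjusted over the list alone), with a median log2 of -0.48 over 17 measured members, although the list's median TPM was higher in replicate 2. Star (log2 -0.94), Cyp11a1 (-0.81) and Cyp11b1 (-0.90) were lower, while Hsd11b1, which regenerates active glucocorticoid and is abundant in liver, was higher by 2.90. Cortical identity genes were lower in 13 of 15 with 2 not called (13 adjusted over the list alone, median -0.55), among them Nr5a1, the steroidogenic master regulator, at log2 -0.84. Zona glomerulosa genes were higher in 2, lower in 11 and not called in 2 (2 and 11 adjusted over the list alone, median -0.39), and zona fasciculata genes higher in 2 and lower in 7 (2 and 7 adjusted over the list alone, median -0.90). X-zone genes were lower in 6 of 7 with 1 not called (6 adjusted over the list alone, median -0.49), and Akr1c18 (-1.62) and the fasciculata gene Akr1b7 (-1.80) lay furthest down. Chromaffin cell genes were lower in 19 of 26 with 7 not called (19 adjusted over the list alone, median -0.63), including Th at -0.99, Dbh at -0.79, Pnmt at -0.68 and Chga at -0.68. The intervals of the steroid synthesis (-0.76 to 0.37), fasciculata (-1.21 to 0.09) and X-zone medians (-1.62 to 0.16) reached 0. Under spike-in scaling the medians were -0.76 (steroid synthesis), -0.83 (cortical identity), -0.67 (glomerulosa), -1.17 (fasciculata), -0.77 (X-zone) and -0.90 (chromaffin). Liver genes were 6.31 higher and lymphocyte genes 3.72 lower on the log2 scale in the same comparison.

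Capsule and stroma genes were higher in 11 of 14 with 3 not called (11 adjusted over the list alone, median 0.75), including the collagen genes Col1a1 (0.93) and Col3a1 (1.00). Macrophage genes were higher in 10 of 13 with 3 not called (11 adjusted over the list alone, median 0.82), C1qa among them at 1.15. Pericyte and smooth muscle genes were higher in all 10 (10 adjusted over the list alone, median 0.46). White adipocyte genes were higher in 11 of 12 with 1 not called (11 adjusted over the list alone, median 0.50), but their median turned to -0.05 on the log2(TPM + 1) scale, where the percentile was 97.2. Brown adipocyte genes were higher in 10 and lower in 1 (10 and 1 adjusted over the list alone, median 0.65), with Ucp1 at 0.65. Schwann and sustentacular cell genes were higher in 2, lower in 1 and not called in 6 (2 higher adjusted over the list alone, median 0.42, -0.24 to 1.12, percentile 97.8), but their median was 0.15 at a mean count of at least 50, where the percentile was 75.4, 0.08 under total-count scaling and 0.005 on the TPM scale. On that scale the medians were also smaller for capsule and stroma (0.25), macrophage (0.36), pericyte and smooth muscle (0.09) and brown adipocyte genes (0.21), and under total-count scaling they were 0.41, 0.48, 0.12 and 0.31. Endothelial genes were higher in 8, lower in 2 and not called in 4 (8 and 2 adjusted over the list alone, median 0.16), which did not stand apart from random lists (percentile 93.9) and turned to -0.11 under spike-in scaling.

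Immediate early genes were lower in 11, higher in 1 and not called in 4 (11 and 1 adjusted over the list alone, median -0.64). Fos, a subunit of the AP-1 transcription factor, was at log2 -1.68, Egr1 at -1.07 and Nr4a1 at -1.24. Cell cycle genes were lower in 12, higher in 2 and not called in 4 (12 and 2 adjusted over the list alone, median -0.25, but -0.52 under spike-in and -0.59 under total-count scaling and -0.50 and -0.63 on the log2(TPM + 1) and log2(TPM + 0.1) scales), the proliferation marker Mki67 at -0.52. Cholesterol synthesis genes went both ways, 7 higher, 11 lower and 2 not called (7 and 11 adjusted over the list alone, median -0.41, -0.83 to 0.36, and -0.69 under spike-in scaling). Dhcr7 (-1.28) and Sqle (-1.02), enzymes of the sterol pathway, were among the lower ones. Each of these medians lay below percentile 2.5, except that of cell cycle genes on the log2(TPM + 1) scale (4.50), and liver genes were 6.31 higher on the log2 scale beside them. Lymphocyte (median -3.72) and erythroid genes (-1.34) were lower in the same comparison.

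Of 34 lists with a value, 8 lay above percentile 97.5 and 11 below 2.5. Among the lists that follow, every median above 0 except that of kidney turned below 0 under spike-in and total-count scaling, and every one, kidney included, on the TPM scale. Lists that did not stand apart included cholesterol uptake and storage (9 higher, 4 lower, 2 not called, 9 and 4 adjusted over the list alone, median 0.18), although its member Apoe, a lipid carrier protein, was 19.2-fold higher. Imprinted genes were higher in 3, lower in 10 and not called in 8 (3 and 10 adjusted over the list alone, median -0.11, but -0.38 under spike-in scaling and -0.51 on the log2(TPM + 0.1) scale). H19 (51.8 and 965 TPM) and Igf2, a fetal growth factor (18.3 and 217 TPM), were 25.6-fold and 13.2-fold higher, and Dlk1 (-0.78) and Meg3 (-0.59) lower. Liver and skeletal muscle genes were higher by medians of 6.31 and 4.75 in the same comparison. Which tissue gave the higher Apoe, H19 and Igf2 was not tested. Glucocorticoid response genes were higher in 6, lower in 4 and not called in 1 (6 and 4 adjusted over the list alone, median 0.14), with the feedback inhibitor Errfi1 at 2.50 and the metallothioneins Mt1 and Mt2 at 1.21 and 1.69. Circadian clock genes split into 5 higher, 6 lower and 5 not called (6 and 6 adjusted over the list alone, median 0.08), and heat shock genes into 4, 2 and 4 (4 and 2 adjusted over the list alone, median -0.07, but -0.35 under spike-in and -0.41 under total-count scaling and -0.47 and -0.54 on the 2 TPM scales). Interferon response genes were mostly not called (2 higher, 1 lower, 8 not called, 2 and 1 adjusted over the list alone, median 0.20), and stood apart only on the log2(TPM + 1) scale (percentile 97.97). Neuronal genes were higher in 4, lower in 2 and not called in 4 (4 and 3 adjusted over the list alone, median 0.18). Ribosomal protein genes were higher in 11 and not called in 7 (11 adjusted over the list alone, median 0.11). Non-coding RNAs were higher in 4, lower in 6 and not called in 3 (4 and 6 adjusted over the list alone, median -0.16), and stood apart only in the second transcript table (percentile 0.790). The X-linked list was higher in 3, lower in 2 and not called in 1 (3 and 2 adjusted over the list alone, median 0.05). Mitochondrially encoded mRNAs were not tested and had a median of -0.02 (-0.30 under spike-in and -0.36 under total-count scaling, -0.44 on the TPM scale). Of kidney, exocrine pancreas and gonad only 2 genes each were measured, with medians of 0.50, -0.55 and -0.33, the last at 0.29 in the second transcript table.

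**Figure D1:**
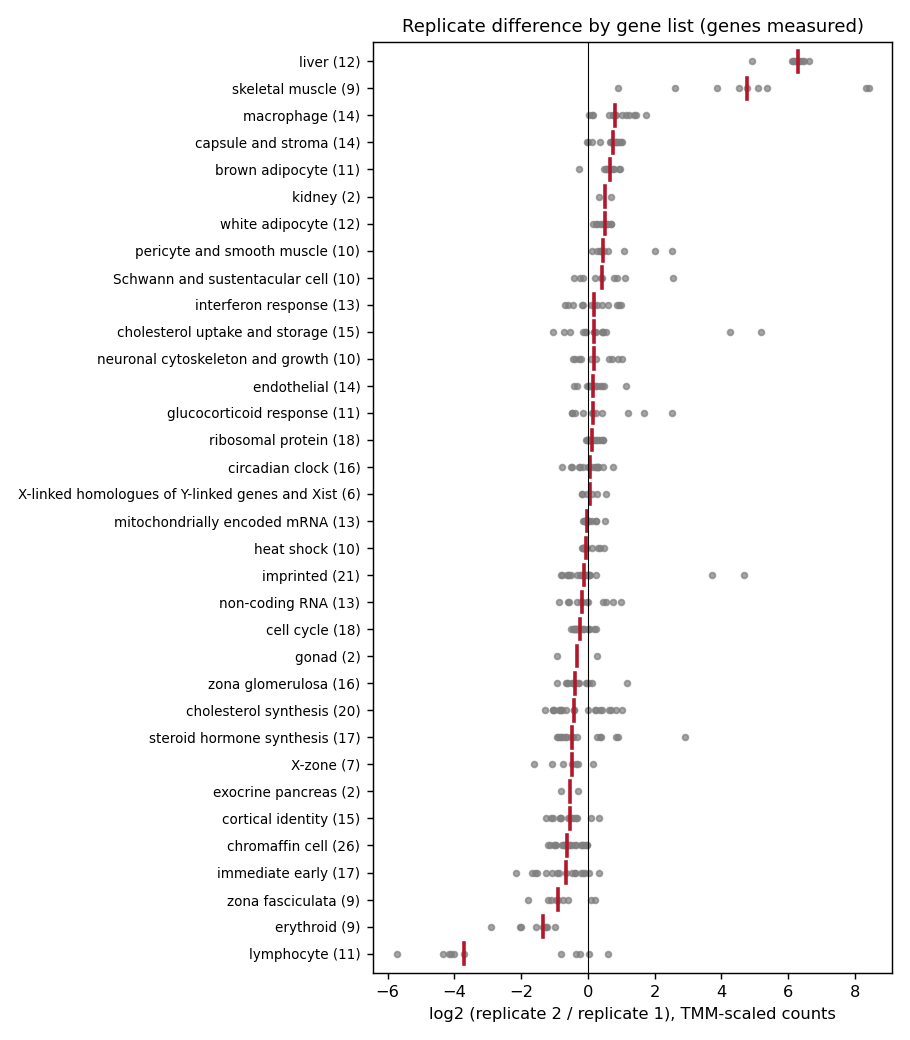
Log2 difference between the libraries (replicate 2 over replicate 1, TMM-scaled counts) for the genes of each list with a mean count of at least 10. Grey points are genes, red bars list medians and numbers in brackets the genes measured. The liver median lies at 6.31 and the lymphocyte median at -3.72, while the adrenal lists lie between -0.90 and -0.39.

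In all, 16137 genes were tested, of which 1346 were over 2-fold higher and 415 over 2-fold lower in replicate 2 (10.9%). An exact conditional binomial test, two-sided with Benjamini-Hochberg adjustment under 0.05, called 4603 higher and 3973 lower. That test compares these 2 libraries and says nothing of conditions, and it rules out a single library deposited under both names. Spike-in scaling put the median gene at -0.28 and total-count scaling at -0.34, against -0.0036 under TMM, while TPM values put it at -0.31. The split of the over 2-fold genes, 76.4% higher under TMM, became 54.1% (1087 higher, 921 lower), 48.9% (1055 and 1101) and 65.7% (769 and 402) respectively. Among binomial calls the share higher was 53.7% under TMM, 22.9% under spike-in scaling and 19.4% under total-count scaling.

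The biological coefficient of variation (BCV) was 0.407 over 16717 genes. Among 29 spike-ins with at least 50 reads in both libraries, the log2 difference had an SD of 0.209 (95% bootstrap interval 0.156 to 0.249). The 270 genes matched to them on mean count had an SD of 1.35, 6.46 times as large (5.42 to 8.68). Unlike the spike-ins, these genes needed no minimum in each library, so genes near 0 counts in 1 library could enter. A robust spread (scaled median absolute deviation) of the same genes was 0.469.

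**Figure D2:**
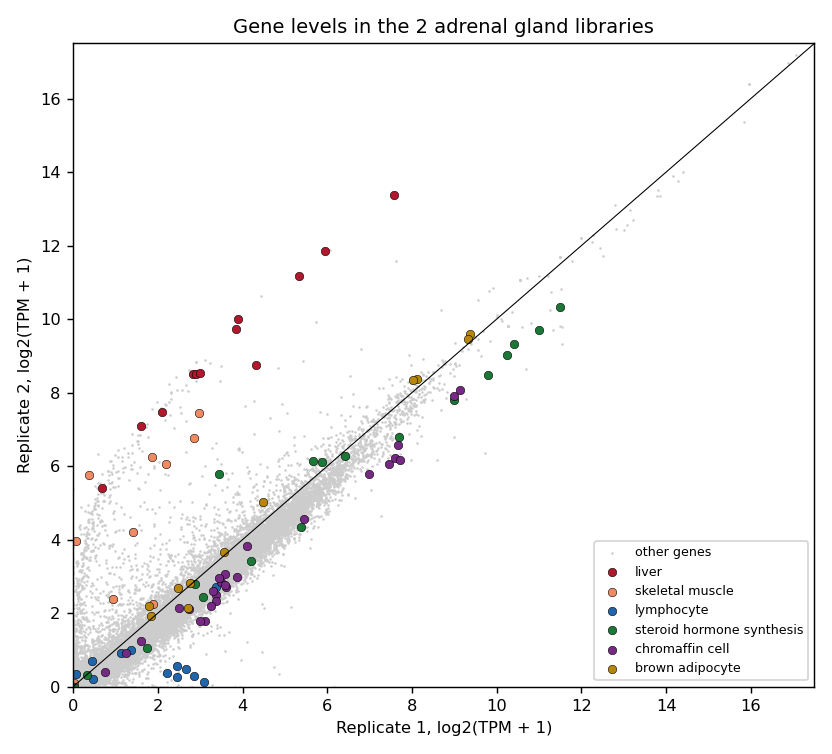
Gene levels in replicate 1 and replicate 2, both as log2(TPM + 1), with the line of equality. Liver and skeletal muscle genes lie above the line, lymphocyte T cell genes below it, and steroid synthesis and chromaffin cell genes mostly slightly below. Alb is the highest liver point, at 189 and 10582 TPM.

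By class, mitochondrial ribosomal RNA took 27.1% (95% Wilson interval 27.1 to 27.1) of counts in replicate 1 and 31.1% (31.0 to 31.1) in replicate 2, and protein-coding genes 62.4% (62.4 to 62.5) and 58.4% (58.4 to 58.4). Small structural RNAs led the TPM table after mt-Rnr1 (142962 ± 8095 TPM) and mt-Rnr2 (124312 ± 6808 TPM). The effective length behind these TPM values was the length less 99 bases, and the class of miscellaneous small RNAs held 3.58% and 4.32% of counts against 18.5% and 21.4% of TPM. Rn7s1 and Rn7s2, 2 copies of the RNA of the signal recognition particle that cannot be separated by sequence, were both listed at 63159 and 85762 TPM. The mitochondrial pseudogene Gm28661, a nuclear copy of mitochondrial DNA, was listed at 18448 and 15289 TPM, so the levels of its mitochondrial counterparts are uncertain.

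Each library has a further deposited transcript table, in which short RNAs were mostly lower and most other genes over 2-fold apart higher. In replicate 1, Rn7s1 was listed at 63159 TPM in the first table and 4.07 TPM in the second, mt-Atp8 at 14774 and 0 TPM, and Rmrp, the RNA of the RNase MRP enzyme, at 7109 and 1.83 TPM. Going the other way, Rpl5 was at 21.9 and 266 TPM, Cycs, cytochrome c, at 29.0 and 214 TPM and Rpl10 at 64.3 and 607 TPM, families with many processed pseudogenes. By the mean log2 ratio over the 2 libraries, all 167 genes shorter than 200 bases were over 2-fold lower in the second table. By the same measure, so were 87.5% of those of 200 to 300 bases and 0.0403% of those of 4000 bases or more. Across 14532 genes the tables correlated with Pearson's r of 0.831 and 0.826 and Spearman's rho of 0.888 and 0.886, across genes that are not independent replicates. In both libraries 705 genes were over 2-fold higher in the second table and 375 lower. The second table's median gene was 0.42 and 0.46 higher on the log2 scale, and relative to it the split was 275 higher and 422 lower. Of 5267 genes with several transcripts, 4669 (88.6%) had the same major transcript in both replicates and 3742 (71.0%) the same one in both tables of replicate 1.

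**Figure D3:**
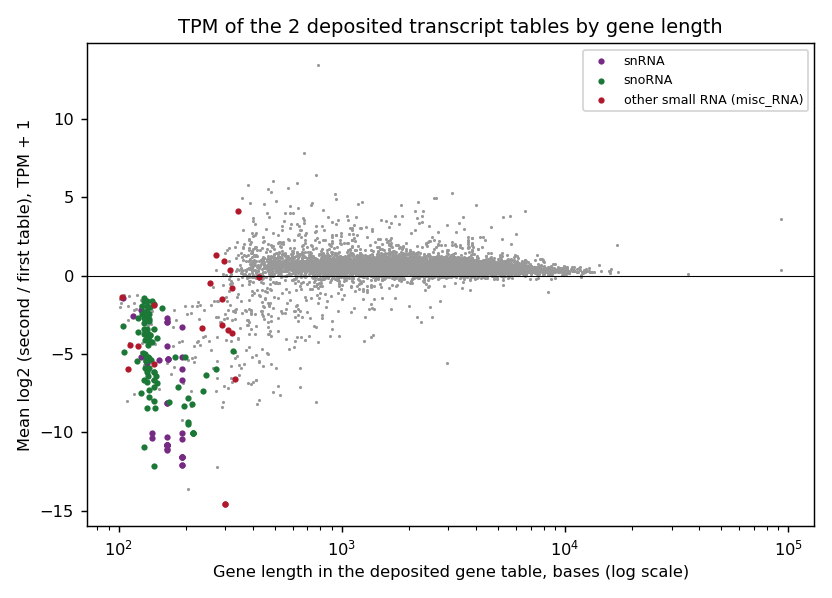
Mean log2 ratio of the second to the first transcript table (TPM + 1, mean over the 2 libraries) against gene length in bases on a log axis, with small RNA classes coloured. Genes under 200 bases all lie below 0, with a median of -4.85.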

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

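The tRNA entries of the gene table, which entered no comparison, summed to 5.69 expected counts in replicate 1, above the 3 counts that a count of 0 allows, and to 2 counts in replicate 2.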

How the results depend on the processing

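The lists and pairs whose changed values are given here were singled out after the values were seen, and the comparison of tables relative to the median gene was added then. Causes were not tested except where the alternative's construction gives one. The exact binomial count stayed within 1.5 times under all 7 alternatives, and 19 lists outside percentiles 2.5 to 97.5 became 17 to 19. In that, 4 lists changed side on the log2(TPM + 1) scale (cell cycle, white adipocyte, Schwann and interferon response), 2 in the second table (Schwann and non-coding RNA), 1 each at mean counts of at least 1 and 50 and on the log2(TPM + 0.1) scale, and 0 under the 3 other scalings. The 24 lists outside for level became 21 to 24, with 9 changing side over members of at least 1 TPM, 3 without either replicate and 2 in the second table, and 8 to 10 of 15 pairs had the numerator higher. DESeq2 size factors moved no value in any of these families beyond its bound.

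Genes over 2-fold lower in replicate 2, 415 in all, became 921 with spike-in and 1101 with total-count scaling. They were 1088 at a mean count of at least 5, 123 at 100 and 4155 with no minimum, which adds or removes genes near the floor. Genes over 2-fold higher, 1346, became 4122 with no minimum and 769 on the log2(TPM + 1) scale. The BCV of 0.407 (a direct common estimate, the one resampled, was 0.411, interval 0.400 to 0.422) became 0.486 without the filter, 0.399 as the trended and 0.353 as the tagwise median. The ratio of gene to spike-in spread, 6.46, became 4.91 with spike-ins of at least 10 reads. Mean Pearson's r between tables, 0.829, became 0.733 at a pseudocount of 0.1, 0.947 with no minimum and 0.624 at 10 TPM or more. Genes over 2-fold apart, 1080, became 580 at 10 TPM or more and 697 relative to the median gene.

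For the list difference, spike-in scaling, total-count scaling, log2(TPM + 1) and log2(TPM + 0.1) gave -0.76, -0.82, -0.77 and -0.93 for steroid synthesis, -0.90, -0.97, -0.90 and -0.999 for chromaffin cell, 0.38, 0.31, 0.21 and 0.23 for brown adipocyte, and 6.03, 5.97, 5.64 and 5.87 for liver genes. Lymphocyte genes gave -3.98, -4.04, -1.84 and -3.01, with -2.27 at a mean count of at least 1 and -2.83 in the second table. White adipocyte genes reversed to -0.0462 and -0.0464 on the TPM scales. The mean list TPM became 103 (second table), 99.1 (without mitochondrial genes and spike-ins) and 72.1 (members of at least 1 TPM) for steroid synthesis, 12.1 and 13.5 for chromaffin cell and 16.1 and 18.2 for brown adipocyte under the first 2. Among pairs, Cyp11b1/Cyp11b2 became 3.63 in the second table and 5.33 as a ratio of counts, and Th/Cyp11a1 -3.11 as counts. As counts, not divided by length, Akr1c18/Cyp11b1 reversed to -0.95 and Pnmt/Dbh to -0.47, and Xist/Eif2s3x reversed to -0.19 in the second table. Over all lists and pairs, 71 of 271 difference values, 67 of 173 level values and 21 of 90 pair values moved beyond their interval or SD, while 2 differences of lists outside percentiles 2.5 to 97.5 and 3 pairs beyond their SD turned sign. List medians inside those percentiles turned sign in 36 further values, over 10 lists. Leaving out a replicate moved no list level or pair beyond its SD, which with 2 replicates is fixed by construction. No paired analysis was possible because there is 1 group. Leaving out a replicate gives no difference between libraries. No value could be had for the kidney and Y-linked levels over members of at least 1 TPM, the gonad difference at a mean count of at least 50, and the Y-linked difference.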

Other observations

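All tests of explanations in this part were chosen after the result was seen, with lists written afterwards. Most markers of other liver cells were higher in replicate 2, among them Stab2 of the sinusoidal lining (28.9-fold, 23.4 to 36.0), Cd5l of Kupffer cells (21.7-fold, 13.9 to 35.5) and Lrat of stellate cells (79.4-fold, 30.6 to 294). List medians were 3.88 for Kupffer cell, 1.04 for sinusoidal, 3.46 for stellate and 1.11 for bile duct genes (log2). Thymocyte genes had a median of -5.32 over 9 measured genes, thymus epithelium genes -2.71 with a count of 0 set to the floor, B lymphocyte genes -0.24 and fat genes not shared with liver or muscle 0.65. The 4 muscle genes of the carry-over check had a median of 7.86 with a count of 0 set to the floor, a lower bound, and of 8.37 without that. Of these lists, all 7 fat genes, 5 of 7 B lymphocyte genes and 2 of the 4 muscle genes also stand in the lists fixed earlier, and all 7 fat genes reached 1 TPM in both libraries. Of the 10 thymocyte genes 2 also reached 1 TPM in replicate 2, and 1 of the 6 thymus epithelium genes did. Genes over 16-fold higher in replicate 2 numbered 508 and took 0.178% (95% Wilson interval 0.176 to 0.179) of counts in replicate 1 and 7.91% (7.91 to 7.92) in replicate 2. Genes over 16-fold lower numbered 36, with 8954 and 121 counts.

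For the first pattern, the height of liver transcripts in replicate 2, liver tissue or its RNA in that preparation is a candidate explanation: 11 of 14 markers of other liver cells were called higher, with a median log2 of 2.14 (0.65 to 4.84), although 6 of the 14 also reached 1 TPM in replicate 1. Reads of a liver library counted into replicate 2 cannot be told apart from tissue, because both give 1 common ratio and the SD over 12 liver genes was 0.431. For the liver signal in replicate 1, where Alb stood at 189 TPM, carry-over of replicate 2 reads cannot be told apart: 4 muscle genes left 0.422% of their replicate 2 count there (upper bound 0.547) against 1.79% for liver genes, but were chosen as near absent from replicate 1, and the fixed muscle list left 4.78%. In a second test, added for that reason, 2 of 16123 genes (Myh1 and Myh2) lay below the lowest share of a liver gene, 1.41%. At least 5 were asked for. Both are among the 4 chosen muscle genes, and without those 4 genes 0 lay below that share, so this test leaves carry-over open too. No biological explanation was tested.

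The second pattern is lower adrenal and higher fat transcripts in replicate 2. Dilution by liver and muscle RNA would lower both alike, whereas fat genes lay above chromaffin genes by 1.28 (1.02 to 1.37). These genes had already been seen to differ, so the value restates the pattern and is no independent test. It shows only that equal dilution alone would not give the pattern. A smaller share of whole gland against surrounding tissue may contribute, since cortical identity and chromaffin genes differed by 0.0758 (-0.26 to 0.25). The other cortical lists did not enter that test. Their medians were -0.90 (fasciculata), -0.49 (X-zone), -0.48 (steroid synthesis) and -0.39 (glomerulosa), against -0.63 for chromaffin genes. Against a single shift of shares, erythroid genes were lower by a median of -1.34 where macrophage genes were higher by 0.82. A change within cells of the gland stays open, and no biological explanation was tested.

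The third pattern is the height of thymocyte transcripts in replicate 1. Thymus tissue in that preparation is a candidate explanation: 4 thymus epithelium genes had a median of -2.71, with 3 of the 4 resting on a count of 0 set to the floor and a wide range before that (-6.41 to -0.34), among them Prss16 (49 and 0 counts, at least 11.6-fold) and Psmb11 (21 and 0, at least 4.98-fold), both few counts, and Ccl25 at 291 and 164. More blood in replicate 1 cannot be told apart over the thymocyte list, because B lymphocyte genes lay above its genes by 5.08 with a wide interval (0.26 to 6.60). A second test, added because that one was undecided, used the 6 T cell genes of the lymphocyte list. B lymphocyte genes lay above them by 3.89 (3.40 to 4.95), and above these pooled with the thymocyte genes by 4.10 (3.44 to 5.45). The 6 genes had already been seen as over 2-fold lower in replicate 2, so the test restates a known difference. It shows only that blood raising T and B cell genes alike would not alone give that difference. Lower erythroid genes (-1.34) leave a part played by blood open. No biological explanation was tested.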
